A study of Arabidopsis thaliana with 72 samples.

How the data were processed

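Transcript levels were measured on Affymetrix arrays in shoots and roots of 6 lines of Arabidopsis thaliana, grown for 21 days on vertical agar plates with 0.4 mM nitrate (low) or 9 mM nitrate (sufficient). El-0 and Fei-0 are accessions, and KB006, NG064, NG087 and SG063 are recombinant inbred lines, the inbred progeny of crosses between accessions. Each of the 24 groups of line, organ and nitrate supply had 3 replicates, which makes 72 arrays. Per the labels, a replicate was biological and was a pool of 30 plants from 3 plates. The labels also give 6 seeds per dish, which does not account for 30 plants from 3 plates, and the sample titles of 4 lines read KB006-0, NG064-0, NG087-0 and SG063-0 where the genotype fields read KB006, NG064, NG087 and SG063. Both forms were taken as the same line, and the form of the genotype field is used.

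The deposited values are log2 expression values per probe set. The submitters' processing notes name affy, GCRMA and limma, with no version, and name no further step; which arrays were normalised together is not given in the sources used here. GCRMA subtracts a background estimated from probe sequence, and the deposited table has a lowest value of 2.11, with 27% of all values within 0.1 of it. A change in a gene that is at this floor in 1 of the compared groups is therefore likely to be an underestimate, and probe sets at the floor carry little replicate spread. The array probes carry the sequence of a reference genome, so a sequence difference in a line can lower a signal with no change in transcript level. No reads are counted on an array, and the number of arrays limits the precision.

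All 22746 probe sets of the table were used, with no filter, no further normalization and no array left out. Gene names came from the table that pairs probe sets with genes and, for symbols, from a gene table of the TAIR10.1 assembly, which was used for names alone; no coordinates are given. Exactly 1 gene was paired with 13513 probe sets (59.4%), several genes with 503 and no gene with 8730, and 13436 of the first were matched to the gene table. Only probe sets with exactly 1 gene were named as genes, which covers 13355 genes.

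Each organ was fitted apart with limma 3.58.1 in R 4.3.3, as a group-means model over its 36 arrays and 12 groups. A fit of all 72 arrays served the comparisons between organs. Contrasts were the low minus sufficient difference averaged over the 6 lines with equal weight, the same difference within each line, a moderated F test of the 5 differences between the lines' responses (line by nitrate interaction), each line's response minus the mean response of the other 5 lines, a moderated F test of the differences between line means, all 15 pairs of lines, the mean shoot response minus the mean root response, and shoot against root. Standard errors are limma's moderated errors. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, a probe set was called at an adjusted p below 0.05, and changes of 2-fold or more (a log2 change of 1) were counted beside it. The words rose, fell and changed are used for called probe sets. Replicate numbers were not used as a block, except in an alternative given with the counts it moved.

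Gene groups came from 27 lists with 462 members written from general knowledge of nitrogen responses, and from 14 lists added from the names in the probe table before any expression value was seen. Of the members of the first 27 lists, 71 had a probe set of their own, and 8 members whose locus carries another symbol in the gene table were left out. Members called measured are those that the probe table pairs alone with a probe set. The array may carry others among the 8730 probe sets with no gene in that table. A list result covers its measured members alone, such as 8 of 41 photosystem genes. Lists with 3 or more measured members were tested with camera (limma), which asks whether a list's genes shifted more than the other genes, with a preset correlation of 0.01 between genes; p-values were adjusted apart over the first 11 and the 14 added lists that could be tested. Members were also counted with p-values adjusted over the list alone. The lists for uptake of ammonium, urea and amino acids, nitrate reduction, ammonium assimilation, early flavonoid steps, phosphate starvation, auxin and brassinosteroid responses of roots to nitrogen, suberin and floral genes had 0 measured members and give no result. For a gene with several probe sets the one with the highest mean was used.

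The genes named were chosen by a rule: in each organ the 10 called rises and the 10 called falls of largest size in the mean response with the same direction in 6 of 6 lines; 19 nitrogen genes named in advance, of which 1, NRT2.5, had a probe set of its own; in each list up to 3 called rises and 3 called falls of largest size; for the interaction, the genes with the 10 smallest p-values of the F test and, per line, the 2 called deviations furthest above and the 2 furthest below the other lines; for the difference between organs, the 5 largest on either side; and for the lines, the genes with the 10 largest F values and called list members whose line means span over 2 on the log2 scale. The other nitrogen genes named in advance were not paired alone with a probe set in the probe table, which does not mean that the array lacks them. Lists, comparisons, the naming rule and a set of alternatives were fixed before the data were examined.

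The alternatives were a filter on probe sets with a mean log2 value below 5, eBayes with trend and robust, arrayWeights, quantile normalization, centring of each array on its median, leaving out 1061 probe sets with a suffix for shared sequence (_s_at or _x_at), replicate number as a block within lines or over all lines, leaving out each replicate, each line or each array of a line, a fit of all 72 arrays, a fit of the 6 arrays of a line and organ alone, and, for lists, all probe sets of a gene, a correlation estimated from the data, and fry. The fry test asks whether a list's genes move on balance one way and makes no comparison with other genes. An alternative chosen after seeing the data left out the 4 arrays labelled Fei-0 replicate 3, whose values did not match their labels; another added the mean of 100 root-enriched probe sets as a covariate for shoots. These 100 root-enriched probe sets, and 100 shoot-enriched ones, are those with the largest mean difference between organs over both nitrate supplies in the 5 lines other than Fei-0, a definition that was widened once after first scores had been seen. Where labels decide a direction, results are given with all arrays as labelled first and without those 4 arrays second.

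The steps were tested on simulated data of 22746 probe sets, 200 of them changed, 100 by 1 and 100 by 2 on the log2 scale, with noise drawn independently for each gene. The simulation left out the 4 arrays labelled Fei-0 replicate 3 and placed changes only in probe sets with a mean above 5. Its rates were thus not measured for probe sets near the floor or for fits that include those 4 arrays. Recovery of changes of 1 and of 2 was 92% and 98% for the mean response in shoots, 99% and 100% in roots, 50% and 92% within 1 line in shoots, 74% and 92% within 1 line in roots, 27% and 67% for the interaction in shoots, 57% and 87% for the interaction in roots, 71% and 93% for line differences in shoots, 86% and 98% for line differences in roots, 85% and 100% for the organ by nitrate interaction, and 98% and 100% for shoot against root. Between 4 and 16 unchanged probe sets were called in these runs. Of 200 lists with no shift, camera gave 15 in shoots and 17 in roots an unadjusted p below 0.05, more than the 5% that the threshold implies. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.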

Results

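Shoots and roots of 6 Arabidopsis lines, chosen for contrasting growth at low nitrogen, were compared between 0.4 mM and 9 mM nitrate on 72 arrays, with 18 arrays per organ and nitrate supply and 3 per line. Array medians lay between 5.72 and 6.04 on the log2 scale. On each array 25.1% to 27.8% of the probe sets were within 0.1 of the lowest value of 2.11, and 54.7% to 57% were above 5.

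LHCB4.2 (AT3G08940), a chlorophyll-binding protein of photosystem II, averaged 13.36 ± 2.76 (SD, n = 18) in shoots and 8.72 ± 1.22 (SD, n = 18) in roots at sufficient nitrate. PRK (AT1G32060), a Calvin cycle kinase, averaged 12.55 ± 2.59 and 7.24 ± 1.54 (SD, n = 18 each). The comparison of shoot with root asked whether values matched the organ labels. Between the organs 15693 probe sets (69%) differed at an adjusted p below 0.05, 6529 higher in shoots and 9164 higher in roots, and 6134 differed 2-fold or more. Without the array labelled Fei-0 shoot at sufficient nitrate, replicate 3, the SD of LHCB4.2 and PRK in these shoots was 0.47 and 0.16. For each array the correlation across probe sets with the mean of each organ and nitrate condition was computed; probe sets are not independent replicates. The best match was the condition on the label for 68 of 72 arrays, with r from 0.951 to 0.991. The other arrays were all 4 of Fei-0 replicate 3. The array labelled shoot at low nitrate matched shoots at sufficient nitrate (r = 0.98, against 0.962 with its own condition). The array labelled shoot at sufficient nitrate matched roots at low nitrate (0.986 against 0.786), the array labelled root at low nitrate matched roots at sufficient nitrate (0.985 against 0.975), and the array labelled root at sufficient nitrate matched shoots at low nitrate (0.983 against 0.857). No array was relabelled; every direction below that involves Fei-0 or a mean over lines rests on these labels, and counts are also given without the 4 arrays, a choice made after the values were seen. With the 4 left out, 15859 probe sets differed between the organs.

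**Figure D1:**
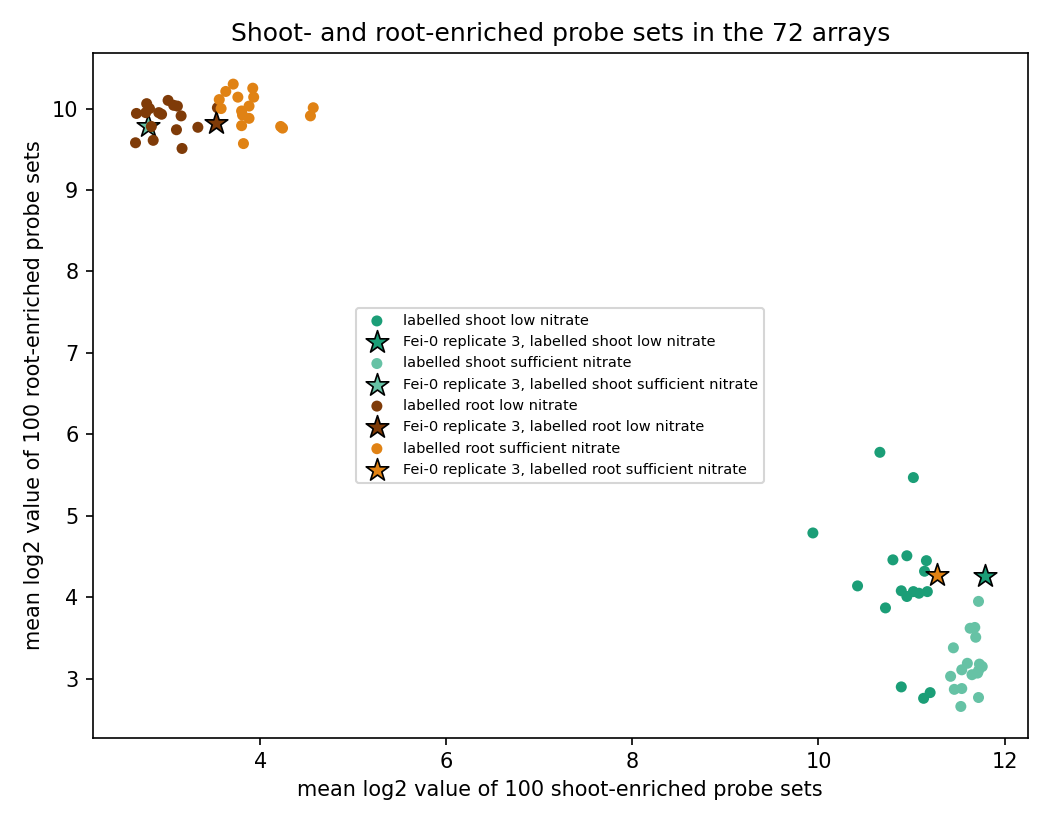
Mean log2 value of 100 shoot-enriched probe sets (horizontal) and of 100 root-enriched probe sets (vertical) in each of the 72 arrays, coloured by the organ and nitrate supply on the label. Stars are the 4 arrays labelled Fei-0 replicate 3, of which the one labelled shoot at sufficient nitrate lies among the roots and the one labelled root at sufficient nitrate among the shoots.

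In shoots, low nitrate raised GRXC14 (AT3G62960), a glutaredoxin, by 5.77 ± 0.37 on the log2 scale (SE; 9.27 ± 1.2 at low and 3.50 ± 1.19 at sufficient nitrate, SD, n = 18 each, adjusted p = 4.56e-11). It raised NRT2.5 (AT1G12940), a high-affinity nitrate transporter, by 5.41 ± 0.37 (8.19 ± 1.48 against 2.78 ± 0.49, SD, n = 18 each, adjusted p = 1.34e-10). AT1G80130 rose by 5.20 ± 0.55, AT1G59950 by 4.90 ± 0.47 and the peroxidase gene PRX52 by 4.52 ± 0.38, followed by AT2G25625, AT1G21520, AT4G33040, AT5G52760 and AT4G00700 with rises of 4.18 to 4.45. The largest falls were those of AT1G49500 (-6.66 ± 0.62; 5.28 ± 2.17 against 11.94 ± 1.72, SD, n = 18 each), AT2G20670 (-6.13 ± 0.58), AT3G28220 (-4.93 ± 0.42) and AT5G19120 (-4.75 ± 0.57). AT1G62510 (-4.47), AT1G54740 (-4.19), the auxin-response gene IAA29 (-4.06 ± 0.66), AT3G15630 (-3.41), AT3G50560 (-3.40) and AT1G78450 (-3.30) completed the 10 falls. All 20 genes had estimates of the same sign in 6 of 6 lines, which were not called in every line (AT1G78450 was at -0.12 in KB006 and -0.11 in Fei-0 as labelled). The highest adjusted p of their mean responses was 4.54e-05, and all 20 were called without the 4 arrays. Of the 10 rises 3 also rose in roots, and of the 10 falls 7 also fell there. Averaged over the 6 lines, 9319 probe sets (41%) changed in shoots, 5381 up and 3938 down, 2291 of them 2-fold or more (1378 up, 913 down). With the 4 arrays left out 11358 changed, 6379 up and 4979 down, and 2966 did so 2-fold or more. The median of the shoot arrays was itself higher at low nitrate (5.98 ± 0.04 against 5.80 ± 0.06, SD, n = 18 each), so centring each array on its median moved the median change by -0.174 and the share of rises among the called from 57.7% to 23.6%. Of 8332 probe sets called only with centred arrays 5211 were at the floor. Among the 12808 probe sets with a mean of 5 or more, 4614 of 7558 called rose as deposited. With centred arrays 3248 of these rose and 4804 fell. By quantile normalization 4736 of all probe sets rose in shoots and 4778 fell. The balance of rises and falls thus moved with the scaling, also among brighter probe sets. Of 7746 called both ways 12 changed sign, but a shift of this size leaves few of them room to do so.

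Most measured genes that release nitrogen from protein and storage compounds rose in shoots. All 3 vacuolar proteases rose, ALPHA-VPE by 1.55 ± 0.42, GAMMA-VPE by 1.49 ± 0.12 and APA1 by 0.69 ± 0.09. Of 11 autophagy genes 8 rose and 0 fell, led by ATG8B (1.4 ± 0.15), ATG1A (1.19 ± 0.11) and APG8A (1.03 ± 0.16). Among 10 genes that recycle nitrogen from ureides, urea, asparagine and amino acids, 6 rose and 0 fell (6 and 2 with each array centred on its median): the asparaginase ASPGB1 rose by 3.27 ± 0.35, the allantoinase ALN by 1.46 ± 0.17 and the ornithine aminotransferase DELTA-OAT by 1.02 ± 0.10. Of 5 senescence genes 4 rose, PPDK by 1.88 ± 0.37, WRKY53 by 1.73 ± 0.43, WRKY6 by 1.59 ± 0.27 and SAG101 by 0.72 ± 0.18. Against the other genes these lists shifted up, with adjusted p = 0.0109 for the proteases, 0.000836 for autophagy, 0.00174 for nitrogen recycling and 0.0343 for senescence. With an estimated correlation the adjusted p was 0.278, 0.278, 0.192 and 0.278, so no call held; without the 4 arrays nitrogen recycling had 0.0285 by that test. Adjusted over the list alone, 3, 8, 7 and 4 members rose and 0 fell.

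Late anthocyanin genes and some glycosyltransferases rose in shoots as well. DFR rose by 3.07 ± 0.59, UGT75C1 by 2.49 ± 0.45, UF3GT by 1.7 ± 0.40 and AT5MAT by 0.80 ± 0.23, while UGT78D2 was not called, which makes 4 of 5 members (4 adjusted over the list alone). The list had an adjusted p of 0.033, 0.453 with an estimated correlation, and 0.0615 without the 4 arrays. DFR rose in El-0 (5.39 ± 1.44) and KB006 (5.59 ± 1.44). Its estimates in NG087, Fei-0 as labelled and NG064 were 2.79, 3.01 and 1.64 with no call, and in SG063 it stayed at the floor of 2.11. No line's deviation of DFR from the other lines passed the test. Of 47 UGT glycosyltransferases 15 rose and 2 fell, or 14 and 2 adjusted over the list alone. UGT76B1 rose by 2.68 ± 0.52, UGT71C1 by 2.14 and UGT87A2 by 2.04 ± 0.15, and UGT76C1 fell by 0.35 and UGT71C4 by 0.27. UGT71C1 is 1 of 100 root-enriched probe sets (mean of 9.35 in roots and 3.65 in shoots) whose mean was higher in low-nitrate shoots. The adjusted p was 0.0406, 0.471 with an estimated correlation, and with each array centred on its median 12 rose and 15 fell.

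All plastid-encoded list members called in shoots were falls. Of 43 genes for photosystem, cytochrome and ATP synthase subunits and related plastid proteins 21 fell and 0 rose, among them ndhJ (-1.67 ± 0.40), ndhK (-1.66 ± 0.29) and atpI (-1.65 ± 0.37). Of 19 plastid-encoded ribosomal proteins and RNA polymerase subunits 17 fell and 0 rose, with rpoC1 at -1.52 ± 0.28 and rps2 at -1.24. Each list had an adjusted p of 1.17e-05, which was 0.471 with an estimated correlation and 0.385 and 0.0865 with arrays centred on their medians, where 29 and 17 members fell. Leaving the 4 arrays out, 40 and 18 members fell with adjusted p = 5.68e-16 and 7.89e-09, which were 0.139 and 0.167 with an estimated correlation. The nuclear photosynthesis lists turned on those arrays. As labelled, 0 of 8 photosystem genes and 0 of 3 Calvin cycle genes were called by limma, at an unadjusted p below 0.05 and adjusted over the list alone as well. The photosystem list had a median of 0.12 and a mean of 0.05 under a test direction of down (adjusted p = 0.967; Calvin cycle 0.933; fry 0.927 for each). Of 5 chlorophyll synthesis genes 2 fell, HEMB1 by 0.77 ± 0.15 and GSA1 by 0.55 ± 0.13 (adjusted p of the list 0.196). With the arrays removed 7 of 8, 3 of 3 and 4 of 5 fell, with adjusted p = 0.00139, 0.00527 and 0.00481 for the lists, each 0.187 with an estimated correlation.

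The remaining shoot lists did not pass the camera test. Among 6 nitrate signalling regulators HHO2 (-2.92 ± 0.26), HHO3 (-2.58 ± 0.31) and NRG2 (-0.55 ± 0.13) fell, the glutaredoxin genes GRXC13 (2.56 ± 0.37) and GRXS11 (0.90 ± 0.25) rose and HHO1 was not called (adjusted p = 0.303). Of 13 CC-type glutaredoxins 4 rose and 7 fell, GRXC10 rising by 3.97 ± 0.44 and GRXS3 and GRXS5 falling by 3.27 ± 0.23 and 3.00 ± 0.40 (adjusted p = 0.194). Sugar transporters of the SWEET family moved both ways, 3 up and 3 down of 14, with SWEET13 at 3.97 ± 0.49 and SWEET2 at -2.48 ± 0.28 (median -0.01, mean 0.19, test direction down, adjusted p = 0.586). The starch genes APL3 (2.18 ± 0.29) and APL4 (2.03 ± 0.35) rose, 2 of 4 (adjusted p = 0.126). Of the glucosinolate genes BCAT4 (0.46 ± 0.17) and UGT74B1 (0.43 ± 0.14) rose, 2 of 3 (0.336; 0 with centred arrays). In addition 5 of 11 tau-class glutathione transferases rose and 1 fell, GSTU25 by 2.88 ± 0.49 and GSTU18 by -1.41 ± 0.34 (0.194). Of 28 expansins and xyloglucan enzymes 5 rose and 8 fell, XTH33 by -2.82 ± 0.44 and EXLA1 by -2.67 ± 0.35 (0.0568). COR15A (2.46 ± 0.43) and LTI30 (1.95 ± 0.44) were among 4 rises of 11 cold and dehydration proteins (0.254; 4 rises and 3 falls with centred arrays). GH3.17 (1.62 ± 0.35) rose and HAT2 (-0.78 ± 0.23) fell. They belong to 16 auxin-responsive genes with 3 rises and 3 falls (0.357; 2 and 11 with centred arrays). Of 7 iron bHLH regulators bHLH115 (1.21 ± 0.18) and ILR3 rose and bHLH121 fell (0.363). Defensins and related genes gave 2 rises and 3 falls of 12, THI2.2 by -3.00 ± 0.26 (0.357). Of 7 ER body genes 0 were called by limma and 2 had an unadjusted p below 0.05 (0.335; fry 0.0964; 5 fell with centred arrays). In the short and the wider list of cytosolic ribosomal proteins 4 of 6 and 15 of 54 rose and 1 and 4 fell, RPS9C by 1.38 ± 0.16 and RPL4A by 0.33 ± 0.07 (0.157 and 0.357). In the wider list 4 rose and 25 fell with centred arrays. Adjusted over the list alone the counts of these lists fixed in advance were 2 rises and 3 falls of nitrate regulators, 2 starch rises, 2 glucosinolate rises, 4 rises and 1 fall of ribosomal proteins, 0 photosystem and Calvin cycle calls and 2 chlorophyll falls.

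Lists with 1 or 2 measured genes were read gene by gene. NRT1.4, a nitrate transporter of leaf petioles, fell by 0.85 ± 0.28 in shoots (adjusted p = 0.0161) and by 2.71 ± 0.23 in roots. F6H1, which makes the iron-mobilising coumarin scopoletin, rose by 3.38 ± 0.49 in shoots and 0.73 ± 0.15 in roots, while the iron regulator PYE was called in neither organ. The cytokinin response regulator ARR15 fell by 1.78 ± 0.35 in shoots and 0.40 ± 0.11 in roots, and ARR16 was called in neither. AUR1, a mitotic kinase, fell by 1.27 ± 0.25 in shoots and PDF1.2 by 2.16 ± 0.57, neither called in roots. PDF1.2b, the clock gene GI, the sulfur marker BGLU28 and the root hair gene EXPA7 were not called in either organ, EXPA7 at -0.50 ± 0.23 in shoots (adjusted p = 0.078). NRT2.5 in roots was 0.89 ± 0.40 (adjusted p = 0.0861), and 1.37 with an adjusted p of 3.21e-06 without the 4 arrays.

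The 100 root-enriched probe sets had a higher mean in low-nitrate than in sufficient-nitrate shoots, 4.15 ± 0.81 against 3.19 ± 0.34 (SD, n = 17 each, without the 4 arrays). They include GSTU25, UGT71C1 and PDF2.5, which rose in shoots by 2.88 ± 0.49, 2.14 and 1.32, as labelled. Without the 4 arrays, 45.6% of the 1623 rises of 2-fold or more in shoots were 2-fold or more higher in roots than in shoots, against 14.9% of all probe sets and 10.2% of the 1343 falls of that size.

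**Figure D2:**
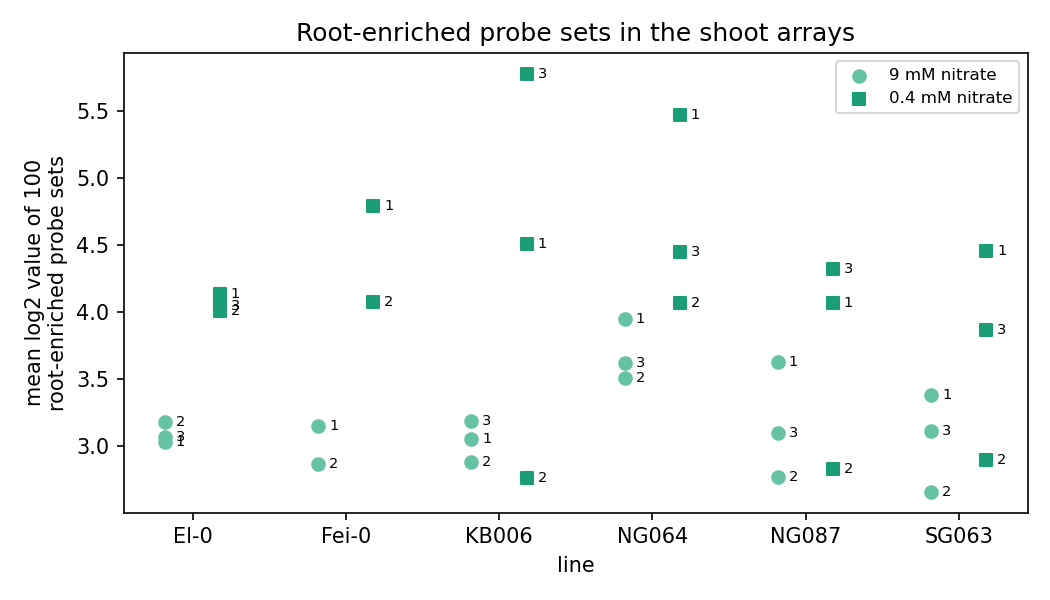
Mean log2 value of 100 root-enriched probe sets in each shoot array, by line and nitrate supply, without the 4 arrays labelled Fei-0 replicate 3; the number beside each point is the replicate. Low-nitrate shoots ranged from 2.76 to 5.78 and sufficient-nitrate shoots from 2.66 to 3.95.

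In roots, the largest rises at low nitrate were those of AT3G28510 (5.72 ± 0.49), AT5G51440 (5.45 ± 0.33), AT2G41730 (4.85) and AT4G32950 (4.48). They were followed by AT3G28580 (4.35), AT2G04050 (4.28), AT2G21640 (4.15), the glutaredoxin gene GRXC10 (AT5G11930; 4.08 ± 0.40), AT2G30670 (4.05) and the sugar transporter gene SWEET14 (4.03 ± 0.24). Falls were led by AT1G78450 (-4.32 ± 0.16), AT5G02160 (-4.26), AT1G49500 (-4.16), PRK (-4.14 ± 0.35; 3.1 ± 1.15 at low and 7.24 ± 1.54 at sufficient nitrate, SD, n = 18 each), the photorespiration gene HPR (-4.14) and LHCB4.2 (-4.10 ± 0.39). Next came AT2G43890 (-4.09), the photosystem I gene PSAN (-3.93), AT1G32470 (-3.92) and AT3G15630 (-3.78). All 20 had the same direction in 6 of 6 lines, with a highest adjusted p of 1.76e-08, and were called without the 4 arrays. Of these, 9 of 10 rises also rose in shoots and 5 of 10 falls also fell there. In total 8331 probe sets (36.6%) changed in roots, 4815 up and 3516 down, and 1434 changed 2-fold or more, 555 up and 879 down. The counts without the 4 arrays were 9726, 5376 up and 4350 down.

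**Figure D3:**
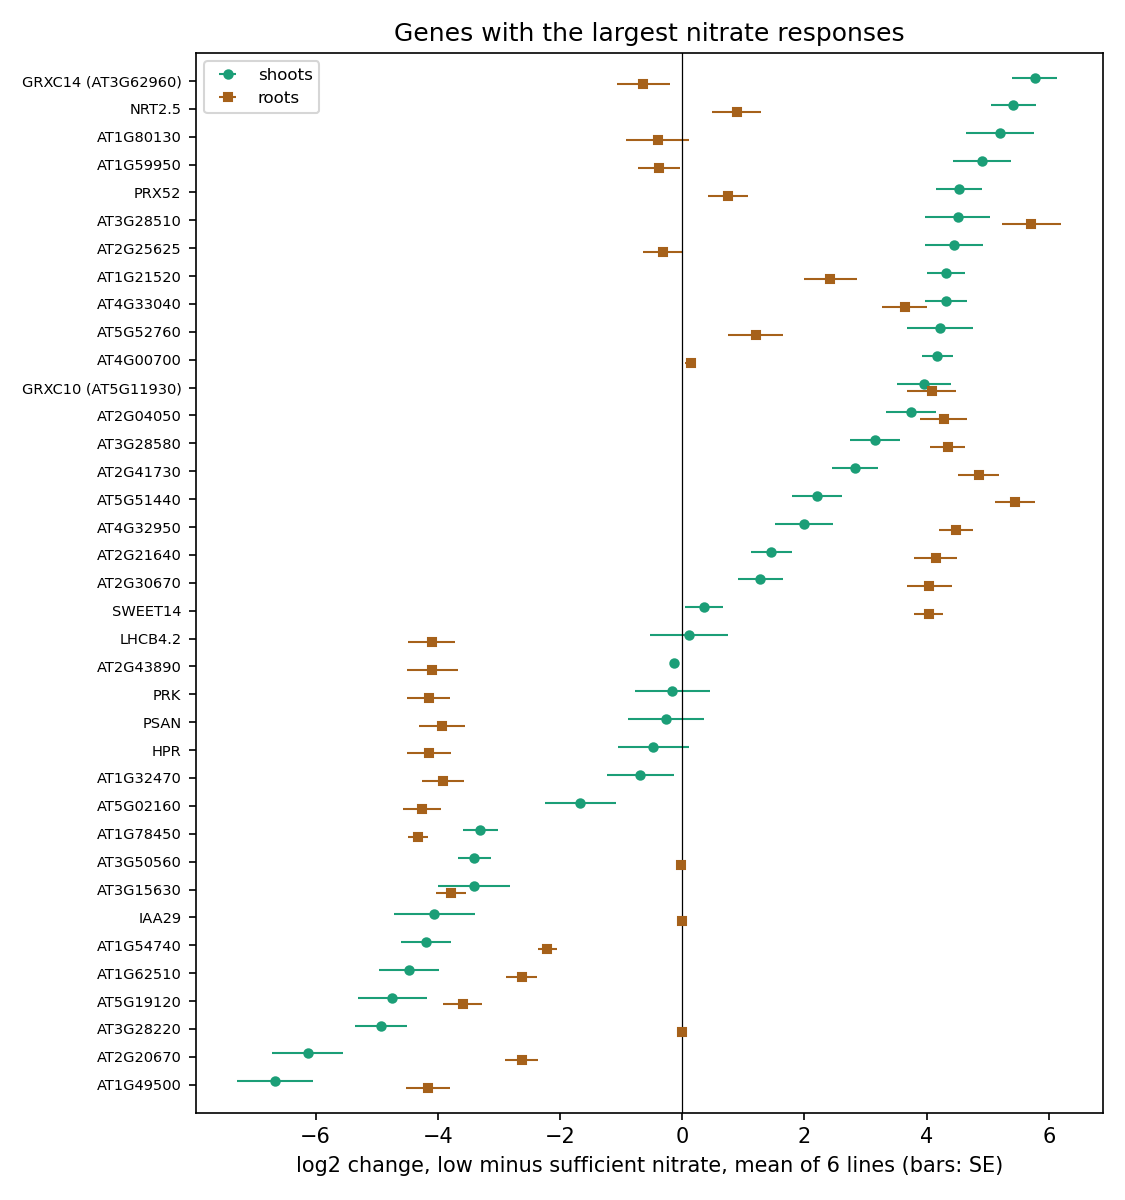
Log2 change at low against sufficient nitrate, averaged over 6 lines as labelled, for the genes with the largest changes in shoots or roots; bars are SE. GRXC14 rose by 5.77 in shoots alone, SWEET14 by 4.03 in roots alone, and GRXC10 by 3.97 and 4.08 in both. A rise called in a single organ is not a test of the difference between the organs.

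Nuclear photosynthesis genes fell together in roots. All 8 photosystem and electron transport genes, all 3 Calvin cycle genes and all 5 chlorophyll synthesis genes fell, the same counts adjusted over the list alone. PSBW stood at -3.30, LHCB4.3 at -1.06, SBPASE at -2.63 ± 0.42, RCA at -2.24 ± 0.27, PORB at -3.69 ± 0.29, CHLM at -2.82 ± 0.23 and CHLP at -2.13. The lists had adjusted p = 5.2e-08, 0.000775 and 1.13e-05, each 0.12 with an estimated correlation, and the chlorophyll list 0.0424 by that test without the 4 arrays. Of the 43 plastid-encoded photosystem and related genes 22 fell, psbC by 2.19 ± 0.23 and psbH by 2.00 ± 0.21 (adjusted p = 6.26e-08; 0.533 with an estimated correlation). Of the 19 plastid ribosomal and polymerase genes 3 fell, rps4 by 1.02 ± 0.18 (adjusted p = 0.321). Among 7 genes of ER bodies and the PYK10 complex, a defence store of roots, 4 fell, JAL22 by 2.25 ± 0.24, JAL33 by 1.35 ± 0.23, NAI1 by 0.79 and NAI2 by 0.61 (adjusted p = 0.01; 0.533 with an estimated correlation). In the same list 6 fell without the 4 arrays (2.91e-06; 0.0683 with an estimated correlation). The wider ribosomal list had 13 rises and 0 falls of 54, led by RPS9C (1.34 ± 0.08) and RPS11B (0.61 ± 0.12). Its adjusted p of 0.00474 was 0.74 with an estimated correlation, 0.107 without the 4 arrays and 0.0718 with centred arrays. The 100 shoot-enriched probe sets had a mean of 2.98 ± 0.24 in low-nitrate and 3.92 ± 0.30 in sufficient-nitrate roots (SD, n = 17 each, without the 4 arrays).

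Other root lists did not pass the camera test. ASPGB1 (1.75 ± 0.20) and AAH (0.42) were among 4 rises and 1 fall of the 10 nitrogen recycling genes (adjusted p = 0.199). ALPHA-VPE (1.18 ± 0.17) and GAMMA-VPE (0.66 ± 0.14) were 2 rises of 3 vacuolar proteases (0.391). ATG8G (0.69 ± 0.07) was among 3 rises of 11 autophagy genes and ATG8F (-0.27 ± 0.06) was the 1 fall (0.408). HHO2 (-0.89 ± 0.20) and HHO3 (-1.01 ± 0.21) fell and GRXS11 (1.04 ± 0.34) rose among the 6 nitrate regulators (0.408). SAG29 (0.58 ± 0.15) was the 1 rise of 5 senescence genes and UGT78D2 (0.39 ± 0.13) the 1 rise of 5 anthocyanin genes (0.546 each). Of 6 ribosomal proteins 2 rose (0.391). In roots 0 glucosinolate (0.546; fry 0.0155) and 0 starch genes (0.881; fry 0.93; median 0.05, mean -0.03, test direction down) were called by limma or had an unadjusted p below 0.05. Adjusted over the list alone these counts were the same. SWEET13 (2.94 ± 0.28) rose and SWEET16 (-1.43) fell, with 2 rises and 3 falls of 14 (0.656; median -0.04, mean 0.25, test direction down). UGT73B4 (2.37 ± 0.23) rose and UGT88A1 (-1.35 ± 0.19) fell among 15 rises and 5 falls of 47 (0.285). GSTU21 (1.86 ± 0.27) and GSTU25 (1.78 ± 0.11) rose among 4 rises and 1 fall of 11 (0.656; median -0.14, mean 0.21, test direction up). EXPB2 (-3.40 ± 0.45) fell and XTH20 (1.43 ± 0.26) rose among 5 rises and 6 falls of 28 (0.656; median 0.01, mean -0.11). LBD16 (0.80 ± 0.19) was among 4 rises of 16 auxin genes (0.428). XERICO (-0.63 ± 0.09) and COR47 (-0.64) were 2 falls of 11 cold proteins (0.418; 4 rises and 2 falls with centred arrays). Iron regulators gave 2 rises and 2 falls of 7, bHLH121 by -0.84 ± 0.07 (0.656; median 0.07, mean -0.16). Defensins and related genes gave 2 rises and 1 fall of 12, GRX480 by 2.71 ± 0.28 (0.822; median -0.01, mean 0.18), and CC-type glutaredoxins had 2 rises and 5 falls of 13, GRXS9 by -0.98 (0.246).

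GRXC14 responded differently in the organs, by 5.77 in shoots and -0.64 in roots, a difference of 6.41 ± 0.57 (SE, adjusted p = 1.3e-12). AT4G39675 (0.64 in shoots, -4.99 in roots) differed by 5.62 ± 0.65, AT1G80130 by 5.60 ± 0.76, AT1G59950 by 5.28 and AT2G25625 by 4.77. On the other side were AT2G39920 (-2.29 in shoots, 3.64 in roots; -5.94 ± 0.52), AT3G28220 (-4.93), AT1G54050 (-4.06; -1.04 and 3.02), IAA29 (-4.06) and AT1G53540 (-3.87; -0.27 and 3.60). The test asked whether the response depends on the organ, and 7702 probe sets passed it, 4193 with the higher value in shoots and 3509 with the lower. The count was 9893 without the 4 arrays and 4410 without replicate 1. With centred arrays it was 14613, and the share with the higher value in shoots went from 54.4% to 19.2%. Photosystem genes had the more negative response in roots: 7 of 8 differed, all with the higher value in shoots (8 adjusted over the list alone; adjusted p = 0.00015). So did 3 of 3 Calvin cycle genes (0.0195), 7 of 11 autophagy genes (8 adjusted over the list alone; 0.00368), 4 of 5 anthocyanin genes (0.0126; 0.0556 without the 4 arrays) and 2 of 3 vacuolar proteases (0.0374). With an estimated correlation all 5 of these lists had an adjusted p of 0.273. The photosystem and Calvin cycle values here are as labelled. Without the 4 arrays most measured photosystem genes and all measured Calvin cycle genes fell in shoots too. The difference is thus not a fall in roots alone. Of 19 plastid ribosomal and polymerase genes 11 had the lower value in shoots (0.00381; 0.389 with an estimated correlation, 0.57 with centred arrays). For the other lists the adjusted p was 0.0759 or more as labelled. With the 4 arrays left out the plastid-encoded photosystem list, 10 up and 21 down of 43, and the ER body list, 5 up of 7, each had 0.0154 (0.425 and 0.315 with an estimated correlation).

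Many probe sets responded in both organs. Both rises were seen for 2579 and both falls for 1400 probe sets, where independent calls would give 1139 and 609. Opposite changes were fewer than independence gives, with 473 up in shoots and down in roots (832) and 318 the other way (834). The counts with the 4 arrays left out were 3302, 2233, 705 and 476, against 1508, 952, 1220 and 1177. Independence was taken over all 22746 probe sets, where 27% of all values were within 0.1 of the lowest. Probe sets without signal in either organ can hardly be called, which lifts every kind of overlap above independence. The size of the excess is thus not read, while opposite changes were fewer all the same.

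Within single lines NRT2.5 rose in shoots of El-0 (5.29 ± 0.90), KB006 (5.97), NG064 (5.72), NG087 (6.53) and SG063 (5.71). In Fei-0 as labelled it was 3.27 (adjusted p = 0.219), and 5.19 ± 0.45 without replicate 3. As labelled, the shoot counts of rises and falls (n = 3 per group) were 1834 and 1088 in El-0, 1480 and 989 in KB006, 1513 and 1094 in NG064, 1498 and 856 in NG087 and 1990 and 1072 in SG063. Fei-0 shoots had 14 called probe sets, 7 up and 7 down, with 2609 at an unadjusted p below 0.05. In roots the counts were 804 and 525 in El-0, 830 and 809 in Fei-0, 2217 and 1704 in KB006, 1927 and 1546 in NG064, 1370 and 1013 in NG087 and 1591 and 1340 in SG063. Leaving out the 4 arrays gave, in shoots, totals of 5734 in El-0, 3590 in Fei-0 (1940 up, 1650 down), 5345 in KB006, 5206 in NG064, 5069 in NG087 and 5792 in SG063, and in roots 3209, 2248, 5828, 5542, 4253 and 4987. The lines share a spread estimate, so those arrays also lower the counts of the other 5 lines. Leaving out single arrays of a line moved its count between 6 and 1086 in Fei-0 shoots, between 103 and 5927 in Fei-0 roots, down to 1131 in shoots of the other lines (NG087) and down to 718 in their roots (El-0), and a block for the replicate number gave 1203 (NG087) to 1818 (SG063) in shoots of those lines; each such array is named with its value in the account of processing choices.

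**Figure D4:**
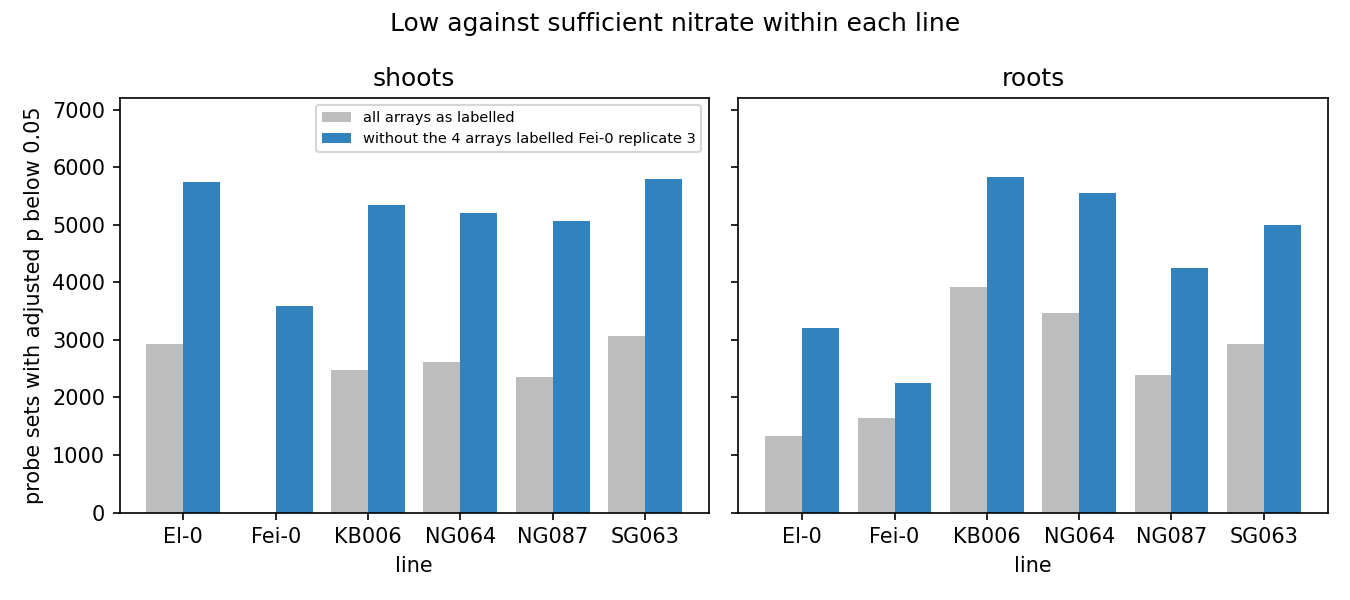
Probe sets with an adjusted p below 0.05 at low against sufficient nitrate within each line, in shoots and roots, with all arrays as labelled (grey) and without the 4 arrays labelled Fei-0 replicate 3 (blue). Fei-0 shoots went from 14 to 3590.

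The probe sets called in all 6 lines in shoots as labelled were 2 rises and 0 falls in limma, chosen after their values were seen: AT1G28570 (1.97 ± 0.14 over the lines, adjusted p = 2.95e-10) and 1 probe set with no gene in the probe table (4.59 ± 0.27, 1.38e-11). At an unadjusted p below 0.05, 200 rose and 124 fell in 6 of 6 lines. In roots 105 rose and 108 fell in all 6. The 5 lines other than Fei-0 shared 417 rises and 246 falls in shoots and 259 and 247 in roots. Without the 4 arrays all 6 lines shared 850 rises and 828 falls in shoots and 357 and 512 in roots.

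Most genes that led the differences in response between the lines were near the floor in several of them. In shoots AT3G53550 fell by 3.74 ± 0.08 in NG064 and stayed at the floor elsewhere, AT2G29000 fell by 2.36 ± 0.06 in KB006, AT1G72920 rose by 3.66 ± 0.19 in KB006 and UBC31 fell by 2.06 ± 0.13 in NG064. The other top genes were AT1G16705 and AT2G43660 (0.63 ± 0.02 and 1.56 ± 0.07 in El-0), AT5G02430 (0.46 in NG064 and 0.35 in NG087), AT5G24480 (-2.04 ± 0.11 in KB006), AT3G44430 (-1.14 in SG063 and -1.07 in El-0) and AT1G72660 (-0.78 in KB006). In roots AT5G54000 rose by 3.39 ± 0.16 in NG087, AT3G25260 by 2.56 ± 0.15 in El-0 and 0.46 in KB006, and AT5G28230 by 3.18 in NG064 and 2.72 in NG087. AT5G59680 fell by 3.83 ± 0.25 in NG087 and 1.27 in SG063, and AT2G18620 fell by 3.03 in KB006 and 2.28 in SG063. The falls of AT1G33320 were called in NG064 (-3.15), SG063 (-2.88), NG087 (-2.01) and KB006 (-0.77), and those of AT3G07350 in KB006 (-2.00), NG087 (-1.29), NG064 (-1.14) and SG063 (-0.84). They were followed by AT5G24480 (-1.40 in KB006), AT2G03130 (1.00 in KB006) and AT1G06540 (0.09 in Fei-0 as labelled). Of the 10 top genes, 10 in shoots and 8 in roots had a line mean below 2.5 in 3 or more lines, and a difference in probe sequence between lines would give the same values. The interaction F test called 182 probe sets in shoots (61 with a mean of 5 or more) and 501 in roots (288), and 253 and 1420 without the 4 arrays. With arrays weighted by their residual spread the counts were 1826 and 3342, and with the replicate number within line as a block 81 and 177. Without probe sets of a mean below 5 they were 13 and 299, and with 1 replicate number left out they went down to 106 (replicate 2) and 132 (replicate 1). In the fits that leave out those 4 arrays, 32 single-gene probe sets in shoots and 465 in roots were called with a mean of 5 or more in every line. Chosen among these after their values were seen, CuAO1, a copper amine oxidase, had shoot responses of 1.16 in El-0 and 0.98 in SG063 but -1.21 in KB006, -1.17 in NG064 and -1.04 in NG087 (adjusted p of the F test 9.24e-06). In the same way AT3G28510 rose in roots by 3.49 in NG064 and 3.34 in NG087 against 7.21 to 8.59 in the other lines (7.59e-06). Its line means were 9.78 in NG064 and 9.71 in NG087 against 6.58 (El-0) to 7.25 (SG063) in the others. The smaller rises thus started from a higher level at sufficient nitrate. A line mean of 5 or more does not keep both nitrate supplies clear of the floor.

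Single lines also set themselves apart from the mean of the other 5. In shoots AT1G53690 fell by 5.81 ± 0.48 in SG063, AT1G77960 and AT4G37220 fell by 4.24 ± 0.37 and 4.06 ± 0.36 in KB006, where AT1G78450 was not called (-0.12). LUP5 rose by 2.44 ± 0.21 in NG087, AT1G65510 rose in NG064 (2.84) and NG087 (2.65), and AT5G16980 rose by 3.91 in El-0 and not in SG063 (-0.02). Near the floor at both nitrate supplies were AT1G78450 in KB006 shoots (mean 2.22) and AT5G16980 in SG063 shoots (2.27). A missing response there cannot be told from a missing signal or a difference in probe sequence. In roots AT5G60250 rose by 4.52 ± 0.51 in NG064, AT2G23440 by 4.05 ± 0.40 in NG087 and AT1G60750 by 3.80 ± 0.31 in KB006, while AT3G05950 fell by 4.34 ± 0.57 in El-0. As labelled 627 probe sets in shoots and 802 in roots set Fei-0 apart, and without the 4 arrays 76 and 224. For the other lines the shoot counts as labelled were 50 in El-0, 72 in KB006, 30 in NG064, 22 in NG087 and 44 in SG063, and the root counts 51, 107, 63, 37 and 53. Without the 4 arrays they were 76, 94, 33, 25 and 63 in shoots and 130, 360, 320, 94 and 125 in roots. KB006 then had the highest count in both organs. Fei-0 had fewer arrays per group in these fits and so larger errors, and its rank against the other lines is not at equal power. The sister lines NG064 and NG087 each enter the mean that the other is set against. A response they share departs less, so their counts do not rank evenly with that of KB006.

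Between lines, averaged over both nitrate supplies, most of the largest differences were presence or absence of a signal. A difference in probe sequence between lines would give the same values. CSA1, an immune receptor gene, had shoot means of 9.25 in El-0, 9.38 in KB006 and 9.50 in SG063 against 2.36 in Fei-0 and 2.32 in NG064 and NG087 (n = 6 each). AT1G58025 was at 10.60 in NG064 and NG087 against 2.12 or less elsewhere, and AT4G29200 at 9.45 in Fei-0 and 10.01 in SG063. AT3G44430 was at 8.37 in El-0 and 8.00 in SG063 and AT4G19500 at 8.25 in KB006. AT5G45500 was at 10.37 in SG063, 6.45 in Fei-0 as labelled and 3.48 or less elsewhere. AT1G23960 and AT2G12050 were highest in Fei-0 (8.87 and 9.25), AT3G59180 in KB006 (7.08) and AT1G59265 in El-0 (7.66). In roots AT3G44430, AT1G58025, AT4G29200, AT1G23960 and AT3G59180 were again among the 10, 5 shared between the organs, beside AT5G39640 (8.52 in KB006), AT5G24480 (7.59 in KB006), AT2G14460 (8.83 in El-0), AT1G03710 (7.17 in El-0) and AT1G70080. Among list members THI2.2 ranged from 3.71 in Fei-0 as labelled to 10.51 in El-0 in shoots, DFR from 2.11 in SG063 to 6.76 in El-0, and GSTU25 in roots from 6.38 in Fei-0 as labelled to 11.61 in KB006. The F test between lines called 5742 probe sets in shoots and 10088 in roots (8162 and 12727 without the 4 arrays). With 1 replicate number left out the counts went down to 2463 in shoots (replicate 2) and 5613 in roots (replicate 1). NG064 and NG087, sister lines of 1 cross, differed in 211 in shoots and 2183 in roots; the other 14 pairs differed in 1307 to 3041 and in 2725 to 4916. Leaving out the 4 arrays gave 460 and 3856 for this pair and 2110 to 3956 and 3024 to 6988 for the others. In roots El-0 and Fei-0 (3024) then had the lowest count, but Fei-0 had fewer arrays per group there, which lowers the power. By differences of 2-fold or more NG064 and NG087 stayed the closest pair in roots, with 359 against 851 for El-0 and Fei-0. A line mean below 2.5 in 1 or more lines was found for 9 of the 10 top genes in shoots and 10 of 10 in roots.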

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

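Of the tests below, the exchange of labels, mixed RNA and another line as the source of the Fei-0 arrays, the level of bright root probe sets in low-nitrate shoots, the single nitrate response, the level of bright shoot probe sets in roots and the lower level in every line were chosen only after the result was seen, as were all values without the 4 arrays labelled Fei-0 replicate 3. The interaction counts, the departures of single lines and the differences between organs stood out by a test of the difference in response itself. The mean responses, the differences between lines and the second pattern below are no such tests and are given beside them.

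Responses differed between lines for 182 probe sets in shoots and 501 in roots, and between organs for 7702. Other splits of the samples gave at most 48, 26 and 217 in 100 draws that include the real split. For the mean response the real count and the highest other were 9319 and 3919 in shoots and 8331 and 2619 in roots. For the differences between lines they were 5742 and 22 in shoots and 10088 and 144 in roots, and for the organs 15693 and 474. In each of these 8 comparisons only 1 of the 100 splits, the real one, gave as many. Real differences that stay in the data widen the residual spread of the other splits and lower their counts. The splits also did not keep samples of the same replicate number together. They make a random origin of these counts unlikely and do not exclude it. Within a line 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real count and the highest other were 2922 and 54 in El-0 shoots, 2469 and 10 in KB006, 2607 and 4 in NG064, 2354 and 4 in NG087 and 3062 and 5 in SG063, and in roots 1329 and 17, 3921 and 16, 3473 and 11, 2383 and 8, and 2931 and 7 in the same order. In Fei-0 shoots the real split gave 14 and 9 of the 10 splits gave as many, 1 of them 6117; in Fei-0 roots the real split gave 1639, 3 of 10 gave as many, and the highest other was 1865. A split that calls many times the real count points to a structure of the Fei-0 samples other than the labelled one.

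Line by line, the response departed from the mean of the other 5 lines for 50 probe sets in El-0 shoots, 627 in Fei-0, 72 in KB006, 30 in NG064, 22 in NG087 and 44 in SG063, and in roots for 51, 802, 107, 63, 37 and 53 in the same order. Without the 4 arrays these counts were 76, 76, 94, 33, 25 and 63 in shoots and 130, 224, 360, 320, 94 and 125 in roots. KB006 was highest in both organs, but Fei-0 had fewer arrays per group there, so the counts are not at equal power. The sister lines NG064 and NG087 also each enter the mean that the other is set against. The largest departures of the interaction genes in shoots were -3.73 for AT3G53550 and -2.00 for UBC31 and 0.40 for AT5G02430 in NG064, -2.36 for AT2G29000, 3.65 for AT1G72920, -2.04 for AT5G24480 and -0.79 for AT1G72660 in KB006, 0.62 for AT1G16705 and 1.54 for AT2G43660 in El-0, and -0.92 for AT3G44430 in SG063. In roots they were -1.40 for AT5G24480, 1.00 for AT2G03130, -1.37 for AT3G07350 and -2.52 for AT2G18620 in KB006, 2.63 for AT5G28230 and -1.97 for AT1G33320 in NG064, 3.39 for AT5G54000 and -3.56 for AT5G59680 in NG087, 2.4 for AT3G25260 in El-0, and 0.09 for AT1G06540 in Fei-0 as labelled. Most of these genes were at the floor in several lines, where probe sequence and transcript level were not separated.

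The response in shoots minus that in roots was 6.41 for GRXC14, 5.62 for AT4G39675, 5.60 for AT1G80130, 5.28 for AT1G59950 and 4.77 for AT2G25625, and -5.94 for AT2G39920, -4.93 for AT3G28220, -4.06 for AT1G54050, -4.06 for IAA29 and -3.87 for AT1G53540.

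Gene lists also shifted in single lines, given as the median of a line's response minus the mean of the others and tested at the preset correlation; in brackets is the lowest adjusted p of these lists with an estimated correlation. As labelled, 0 members of these lists departed by themselves in the lines other than Fei-0. In El-0 shoots the late anthocyanin list stood at 2.12, vacuolar proteases at 0.72, autophagy at 0.48, plastid-encoded photosystem genes at -0.42, CC-type glutaredoxins at -0.91 and the wider ribosomal list at -0.21 (0.385). KB006 shoots had anthocyanin genes at 1.57, ER body genes at 0.92 and the short and wider ribosomal lists at 0.19 and 0.25 (0.562), NG064 shoots the ribosomal lists at 0.31 and 0.29 (0.679), and NG087 shoots plastid-encoded photosystem genes at -0.35, ER body genes at -0.83 and the wider ribosomal list at 0.09 (0.825). In SG063 shoots, where DFR stayed at the floor, anthocyanin genes stood at -2.92, plastid-encoded photosystem genes at -0.44 and plastid ribosomal and polymerase genes at -0.34 (0.382). In roots El-0 had autophagy at 0.14, the ribosomal lists at -0.23 and -0.33, plastid-encoded photosystem genes at 0.42 and plastid ribosomal genes at 0.51 (0.476), NG064 had autophagy at -0.26 and the wider ribosomal list at 0.16 (0.689), and SG063 had SWEET genes at -0.32, ER body genes at -0.53, glutaredoxins at 0.76 and the wider ribosomal list at 0.17 (0.0168). Without the 4 arrays the call ended in shoots for plastid-encoded photosystem genes of El-0, NG087 and SG063, plastid ribosomal and polymerase genes of SG063, the anthocyanin and short ribosomal lists of KB006 and the wider ribosomal list of NG087. In roots it ended for autophagy and plastid-encoded photosystem genes of El-0, and in both organs other calls began, such as plastid-encoded photosystem genes at 0.304 in NG064 shoots. With an estimated correlation between genes only the SG063 root glutaredoxins kept an adjusted p below 0.05 as labelled (0.0168), and without the 4 arrays 3 lists in SG063 roots did, SWEET genes (0.0217), defensins and glutaredoxins (0.0447 each).

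As labelled, Fei-0 departed most. In its shoots photosystem genes stood at 3.20 above the other lines, Calvin cycle genes at 3.47, chlorophyll synthesis at 1.87, plastid-encoded photosystem genes at 1.5, plastid ribosomal genes at 0.91 and glutaredoxins at 1.26, with the ribosomal lists at -0.35 and -0.36 (0.378 or more with an estimated correlation). In its roots the values were -2.53 for anthocyanin genes, -1 for starch, -0.98 and -0.89 for the plastid-encoded lists, 1.74 for ER body genes, -1.21 for glutaredoxins and 0.16 for the wider ribosomal list (0.322 or more). Without the 4 arrays the values in Fei-0 shoots were -0.36 for photosystem genes, -0.39 and -0.23 for the plastid-encoded lists and -0.12 for the wider ribosomal list. In Fei-0 roots they were -1.5 for anthocyanin genes, -0.34 for glutaredoxins and -0.19 for the wider ribosomal list, and the calls of the other lists named for Fei-0 ended.

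The first pattern weighed is this departure of Fei-0. A mixture of shoot and root RNA is argued against for the array labelled shoot at sufficient nitrate alone. There the 100 shoot-enriched probe sets had a mean of 2.79, within the 2.66 to 4.57 of the other root arrays. The other shoot arrays had 9.94 to 11.76. The rest of the 4 arrays were not tested for it. The array labelled shoot at low nitrate, which matched shoots at sufficient nitrate, had a root-enriched mean of 4.26. This lay above the 2.66 to 3.95 of the other sufficient-nitrate shoots, so some root RNA stays open there. Another line as the source is argued against by 7 probe sets high in Fei-0 alone, whose mean was at least 7.5 in the 4 arrays, against at least 7.44 in the other Fei-0 arrays and at most 3.37 in other lines. An exchange of labels among the 4 arrays of replicate 3 also stays open. In its test the 4 arrays matched 4 distinct conditions, each of the 4 once, and 0 matched its own label. An exchange would give this. A nitrate response of Fei-0 that differs from the other lines stays open only for what is left without these arrays, and no array was relabelled.

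The second pattern is the higher level of root-enriched probe sets in shoots at low nitrate, where 93 of 100 had a higher mean, 64 rose and 1 fell without the 4 arrays, by a median of 0.90 (19 rose and 1 fell as labelled). For a single response to nitrate of equal size in every array, 4 of the 17 low-nitrate arrays lay within the range of the sufficient-nitrate shoots. This count decides nothing by itself, since the range pooled lines of different levels and an NG064 array set its top. Replicate 2 of KB006 (2.76), NG087 (2.83) and SG063 (2.9) lay below the highest sufficient-nitrate array of its own line. Replicate 3 of SG063 (3.87) lay above all of its line. In these 3 lines replicate 2 was also the lowest at sufficient nitrate. The KB006 arrays, with 2.76 to 5.78 at low and 2.88 to 3.19 at sufficient nitrate, argue against an equal size in that line. Root tissue carried over with the shoots is consistent with a mean pairwise correlation of 0.633 among the 100 probe sets over low-nitrate shoot arrays, where 100 random sets gave at most 0.036; the 10 lowest shoot to root ratios of bright root probe sets (1.62% to 4.17%, median of the set 1.92%) decide nothing, since the set was chosen for low ratios. EXPA7, a root hair gene outside the set and the only member of the root marker list measured, fell by 0.30 in shoots without the 4 arrays. As 1 gene whose level in roots was not compared it decides nothing, and carry-over stays open. A change of expression in shoots that varies between samples or goes with the replicate number stays open, untested, and with the set's mean as a covariate 1255 of 1623 2-fold rises and 1086 of 1343 2-fold falls stayed 2-fold.

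The third pattern is the fall of photosynthesis genes in low-nitrate roots, and the values for it leave out the 4 arrays. For shoot tissue carried over with sufficient-nitrate roots, a first measure, the 7.8% of bright shoot probe sets with a root to shoot ratio under 1/4 of the median of the photosynthesis genes, lay between its bounds of 2 and 10 and decided nothing by itself. A later measure argues against carry-over of whole shoots, since the 10 lowest ratios of bright shoot probe sets reached only 0.165% where the photosynthesis genes had a median of 4.91% at sufficient and 0.819% at low nitrate; a part of the shoot poor in those lowest transcripts stays open. A lower level in roots of every line stays open, since its test (100% of the 96 responses of 16 genes in 6 lines below 0) restates the fall and decides nothing.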

How the results depend on the processing

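Leaving out the 4 arrays labelled Fei-0 replicate 3, the use of the root-enriched mean as a covariate, the scalings of single gene lists and the reassignment of replicate numbers were chosen only after the data were seen; the other alternatives were planned. Quantile normalization and eBayes with trend and robust left every count that answers a comparison within 1.5 times its value and moved no direction of a named gene; by quantile normalization 8 of the named responses lost their call. For each alternative below the cause of a change was not tested unless it is given.

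Without the probe sets of a mean below 5 the interaction called 13 in shoots and 299 in roots, Fei-0 shoots 8, and 1 rise was shared by all 6 lines in shoots; fewer probe sets are tested, and many of those left out are near the floor, where spread is small. Leaving out probe sets with an _s_at or _x_at suffix gave 8 in Fei-0 shoots. Requiring 2-fold changes left 47 rises shared by all lines in roots, down from 105.

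Array weights raised the counts, and their estimation gave convergence warnings in some fits. The interaction was at 1826 in shoots and 3342 in roots and the line differences in shoots at 10660. Within lines the shoot counts were 5330 in Fei-0, 6782 in KB006, 7210 in NG064, 7989 in NG087 and 7760 in SG063, and the root counts 4596 in El-0, 6515 in KB006, 6703 in NG064, 6182 in NG087 and 5594 in SG063. By construction the weights lower the part of arrays far from their group, which includes those of Fei-0 replicate 3.

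Centring each array on its median gave 16078 probe sets in shoots, 13646 in roots and 14613 for the difference between organs, and within lines in shoots 8219 in El-0, 8486 in KB006, 8743 in NG064, 7829 in NG087 and 9087 in SG063. The share of rises went from 57.7% to 23.6% in shoots, from 57.8% to 75.1% in roots, from 54.4% to 19.2% for shoots minus roots and from 41.6% to 58.2% for shoot against root, and the median change from 0 to -0.174 in shoots and -0.204 for shoots minus roots. Part of this follows from the construction, since 5211 of the 8332 newly called probe sets in shoots and 4360 of 5466 in roots were at the floor, where centring adds the array's shift to a constant. IAA18 in shoots turned from 0.15 to -0.03 (adjusted p = 0.66). Signal over background thus limits what the smallest changes and the genes near the floor can show. Quantile normalization moved the share of rises from 57.7% to 49.8% in shoots and from 54.4% to 44.4% for shoots minus roots.

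With the replicate number within line as a block the interaction called 81 in shoots and 177 in roots, and the shoot counts were 1461 in El-0, 63 in Fei-0, 1360 in KB006, 1548 in NG064, 1203 in NG087 and 1818 in SG063; a block shared by all lines gave 7 in Fei-0 shoots. A block takes up degrees of freedom, but in shoots of several lines the numbers also went with the residuals. Residuals of low and sufficient nitrate with the same number correlated above 0.1 for 11 of 18 pairs in shoots and 3 of 18 in roots, and those of shoots and roots for 9 of 18 at low and 5 of 18 at sufficient nitrate. Over the 5 lines other than Fei-0 the mean correlation was 0.148 between the nitrate supplies in shoots, 0.007 in roots, 0.077 between the organs at low and 0.066 at sufficient nitrate. In the same order 14, 3442, 8 and 202 of 7776 reassignments of the numbers within lines gave as high a mean (0.18%, 44.3%, 0.103% and 2.6%). On average over these 5 lines samples with the same number were thus more alike than others, except between the nitrate supplies in roots, but not in each line. The real numbers gave the highest mean in 4, 1, 3 and 4 of the 5 lines, and El-0 had negative correlations between the organs at sufficient nitrate (-0.151, -0.068 and -0.121). Counts that the block lowered depend on this choice.

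Leaving out the 4 arrays gave 11358 probe sets for the mean response in shoots and 9726 in roots, 8162 and 12727 for the lines, 9893 for the difference between organs, and 253 and 1420 for the interaction. Within lines it gave 5734 in El-0, 3590 in Fei-0, 5345 in KB006, 5206 in NG064, 5069 in NG087 and 5792 in SG063 shoots, and 3209 in El-0, 5542 in NG064, 4253 in NG087 and 4987 in SG063 roots, with 850 rises and 828 falls shared by all lines in shoots and 357 and 512 in roots. Added lists past the test for the difference between organs went from 1 to 3. The starch list in roots turned up (adjusted p = 0.418), as did the wider ribosomal list for shoots minus roots (0.787). Of 209 named responses 207 kept direction and call. Deviations of single lines are not among these. The Fei-0 deviations chosen for their size lost their call, such as SUFE2 in shoots (adjusted p from 0.0139 to 0.173) and AT4G39675 in roots (0.023 to 0.202). AT1G06540 in Fei-0 roots, chosen by the F test and near the floor, kept its call with a deviation of 0.09. With the root-enriched mean as a covariate as well, 9220 probe sets changed in shoots.

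A fit of the 6 arrays of a line alone gave 1363 in El-0, 0 in Fei-0, 4525 in NG064, 3651 in NG087 and 5069 in SG063 shoots and 0 in Fei-0 roots, where limma on all 36 arrays called 14 and 1639 (2609 in Fei-0 shoots at an unadjusted p below 0.05). The fit of 72 arrays gave 5133 in El-0, 60 in Fei-0, 4850 in KB006, 4786 in NG064, 4634 in NG087 and 5350 in SG063 shoots, and 608 in El-0, 265 in Fei-0, 1254 in NG087 and 1802 in SG063 roots; it uses a spread averaged over the organs.

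For gene lists an estimated correlation left 0 past the camera test in shoots, 0 in roots and 0 for shoots minus roots, both for the first lists (4, 3 and 5 with the preset) and for the added ones (4, 3 and 1). By fry 9 and 12 lists passed in shoots, 7 and 10 in roots and 9 and 11 for shoots minus roots. With fry the direction turned for photosystem genes in shoots (0.927) and, in roots, for starch (0.93), SWEET genes (0.239) and defensins (0.158). All probe sets of a gene in place of the brightest changed none of the 75 list results.

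Leaving out 1 replicate number from every group gave 5957 (without replicate 2) to 9613 in shoots and 5459 (without replicate 1) to 7907 in roots for the mean response, 106 (without replicate 2) to 188 and 132 to 262 for the interaction (132, 262 and 192 in roots without replicates 1, 2 and 3), 2463 (without replicate 2; 3160 without replicate 1) to 3850 and 5613 (without replicate 1; 6547 without replicate 2) to 8908 for the lines, 4410 (without replicate 1) to 8042 for the difference between organs and 14574 to 15032 for shoot against root. Fewer arrays lower the power by construction. Leaving out a whole line kept the mean responses, the organ by nitrate count and the organ count within 1.5 times.

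Single arrays moved the counts within lines in shoots between 1141 and 2678 in El-0, 6 and 1086 in Fei-0, 1214 and 2016 in KB006, 1406 and 1973 in NG064, 1131 and 2169 in NG087 and 1625 and 2517 in SG063. The arrays whose loss moved a shoot count over 1.5 times were, at low nitrate, replicate 1 of El-0 (1141), replicates 1 (6), 2 (7) and 3 (622) of Fei-0, 1 (1455) and 3 (1214) of KB006, 1 (1608) and 2 (1406) of NG064, 1 (1216), 2 (1131) and 3 (1435) of NG087 and 1 (1989) and 2 (1625) of SG063. At sufficient nitrate they were replicates 1 (1086), 2 (914) and 3 (131) of Fei-0, 2 (1561) of KB006 and 1 (1198) of NG087.

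In roots single arrays gave 718 to 1023 in El-0, 103 to 5927 in Fei-0, 2958 to 3584 in KB006, 2304 to 3257 in NG064, 1522 to 2432 in NG087 and 1929 to 2409 in SG063. Counts moved over 1.5 times without replicates 1 (718) and 3 (803) of El-0, 1 (272), 2 (103) and 3 (2596) of Fei-0, 1 (2304) of NG064 and 1 (1542) and 3 (1523) of NG087 at low nitrate, and without replicates 1 (849), 2 (851) and 3 (867) of El-0, 1 (5357), 2 (5927) and 3 (490) of Fei-0, 3 (2312) of NG064, 1 (1522) of NG087 and 1 (1929) of SG063 at sufficient nitrate. With 1 array gone the other arrays of its group stand for its spread.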
